A study of Arabidopsis thaliana with 36 samples.

How the data were processed

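Roots of Col-0, cap-h2-2 and crwn1/4 seedlings were compared on 36 Agilent arrays, 4 in each of 9 groups of genotype and time in zeocin. Per the labels' protocols, seedlings grew for 2 weeks on gellan gum with MGRL medium, were moved to liquid medium for 3 h and then received 10 µM zeocin. RNA of whole roots was labelled with Cy3. The deposited spot intensity was made with Feature Extraction 10.7.3.1, per the file headers: spots were background-subtracted and detrended within the array (gProcessedSignal), and flags mark spots that are not uniform, saturated or not well above background. RMA and limma are named in the submitters' processing notes, without role or version. The authors' series table holds 36971 probes on a scale found to be log2-like from the values: column medians lay between 6.90 and 7.10, and each column correlated across probes with its own array with r between 0.974 and 0.988. How the authors centred it is not given in the sources used here, so it served only as an alternative.

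From the intensities, log2(gProcessedSignal) was taken relative to each array's 75th percentile. Control spots and spots with an outlier mark were left out, and repeat spots of a probe were averaged. Of 52586 probes, 32878 carry a gene locus (32781 loci, of which 32316 matched the reference table of gene names). A gene was tested where a probe was well above background on all 4 arrays of at least 1 group and had at least 3 unmarked arrays in each group, which left 25122 genes. The brightest such probe stood for its gene, and none of the 96 genes with 2 probes had probes called in opposite directions. A bound ("at least") sets the bright group's mean against the dim group's mean of, per array, the lowest signal well above background or, if higher, the probe's own. The number of arrays limits the precision.

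Group means of all 36 arrays were fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 27 residual degrees of freedom), and p-values were adjusted by the method of Benjamini and Hochberg within each comparison, with calls at an adjusted p under 0.05. There were 19 comparisons: times within a genotype, mutants against Col-0 at a time, and differences between zeocin responses. 19 gene lists (291 genes, 280 tested) fixed before the data were examined were tested with camera at a preset correlation of 0.01 and adjusted over the lists of a comparison. Of 106 list calls, 17 held with an estimated correlation: the DNA damage response (DDR) targets in all 9 zeocin comparisons, in cap-h2-2 at 0 h and in both 3 h differences, the clock genes from 1 to 3 h in each genotype, the hypoxia genes in cap-h2-2 at 0 h and the root tip markers in the crwn1/4 difference at 3 h. Nothing in the labels says that replicates came from separate plants or cultures, so p-values measure the spread between these samples, which may be technical. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were also used.

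The rule for named genes, fixed before the data were examined, ranked called genes by size of log2 fold change, with the 4 arrays of a group all above those of the other except for differences between responses. It allowed up to 12 rises and 12 falls at 1 and 3 h in Col-0 and for each mutant at 0 h, and up to 5 and 5 elsewhere, beside the mutated genes and list members. The text names fewer: the top 8 and 8, or 2 and 2, with list examples of the largest change in their list's direction. These numbers and examples were settled after the values and their dependence on settings had been seen, and no ranked gene was passed over for a lost call. Among the 245 results of named genes, 44 lost their call without some array and 84 under some other setting.

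On simulated data of 24728 genes with complete values, genes changed 1.5-fold, 2-fold and 4-fold were found in 46.3, 73.1 and 97.0% for cap-h2-2 against Col-0 at 0 h, 49.3, 77.6 and 98.5% for 3 h in Col-0 and 31.3, 56.7 and 81.8% for the cap-h2-2 difference at 3 h, with 5.26%, 1.96% and 8.87% false calls. Alternatives were normexp background correction (offset 50), quantile normalization, the series table, other filters and probe rules, slide, scan date or replicate number in the model, the compared arrays alone, another variance model, and each array left out. Replicate numbers were not taken to pair arrays: same-numbered arrays of different groups deviated together with a mean r of 0.0326, against 0.104 on the same slide, and in 3 of 36 pairs of groups every r was over 0.1. Of these, only Col-0 and cap-h2-2 at 1 h are compared, and the number pairs arrays there only for other splits of them.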

Results

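Gene expression was measured in whole roots of 2-week-old Arabidopsis thaliana seedlings with 36 single-colour arrays. The roots came from 3 genotypes: the wild type Col-0, cap-h2-2, which carries a mutation in a subunit of condensin II, and crwn1/4, which lacks a pair of nuclear lamina proteins. Condensin II shapes chromosomes, and the lamina lines the inner face of the nuclear envelope. Each genotype was sampled before treatment (0 h) and after 1 or 3 h in 10 µM zeocin, an antibiotic of the bleomycin family that breaks DNA strands, with 4 arrays per group. Between 29181 and 42960 of 52586 probes were well above background on an array: 36495 to 42960 at 0 h, 29181 to 37780 at 1 h and 30115 to 38810 at 3 h. Arrays of a group correlated across genes with r between 0.974 and 0.995. All 12 arrays of 0 h were scanned on scan day 4, which held only 2 others, 1 each of cap-h2-2 and crwn1/4 at 3 h, and no day held 0 h and 1 h arrays. Untreated roots of 1 and 3 h were not analysed here, so each zeocin comparison also holds the time in solution and the scan day. Values below are log2 fold changes ± the standard error (SE) of the limma fit, n = 4 arrays per group. "At least" marks a bound for a gene whose probe was not well above background on every array of the lower group, with the number of arrays that measured it where some did. Genes were ranked by fitted change, and those with a bound, or unmeasured in a group (no array well above background), have no order of size. A call is an adjusted p (padj) under 0.05, and arrays are named by group and replicate (rep). Counts adjusted over the list alone are given where they differ from those over all genes. Settings that ended a call or moved a count by over 1.5 times are named, except for lists given only as passing. Slide and scan date mean added terms, own arrays the compared groups' alone and unfiltered no filter on dim probes.

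**Figure D1:**
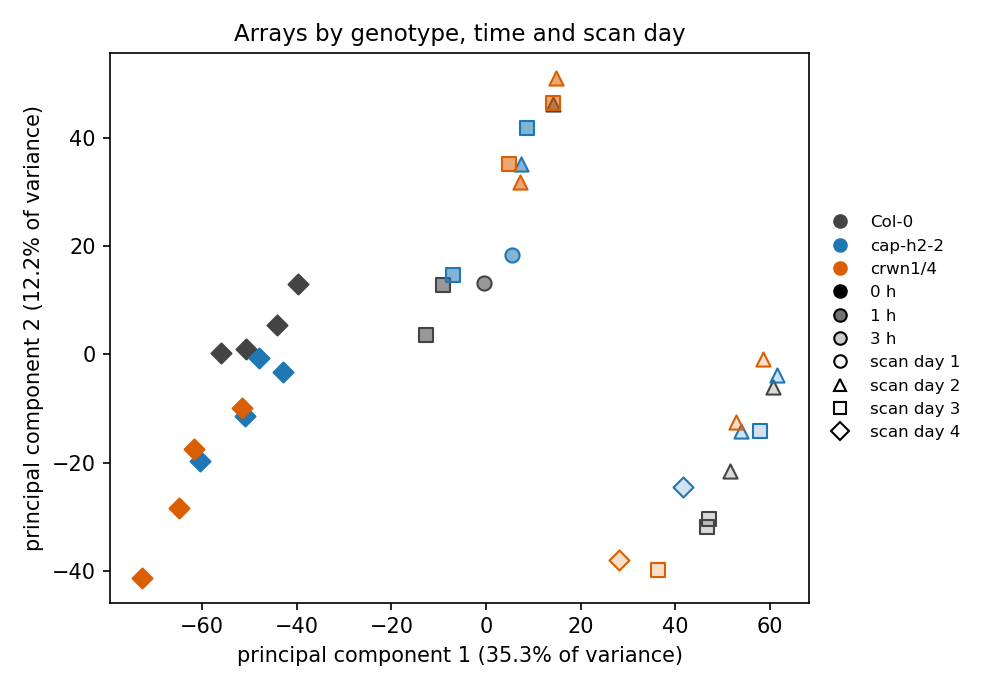
Principal component 1 (horizontal, 35.3% of variance) against component 2 (vertical, 12.2%) of the 36 arrays, by genotype (colour), time in zeocin (fill) and scan day (marker shape). The 12 arrays of 0 h reach at most -39.8 on component 1, and the 3 h arrays scanned on the day of the 0 h arrays lie at 28.1 and 41.6.

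The mutated genes were compared first, since they check the genotype labels. CAP-H2 (AT3G16730) was lower in cap-h2-2 than in Col-0 by a log2 fold change of -5.07 ± 0.20 (at least 8.84-fold) at 0 h, -4.03 ± 0.20 (at least 4.89-fold) at 1 h and -4.47 ± 0.20 (at least 6.72-fold) at 3 h. CRWN1 (AT1G67230) was lower in crwn1/4 by -7.50 ± 0.64 (at least 108-fold, measured on 2 of 4 arrays) at 0 h, -9.94 ± 0.64 (at least 250-fold) at 1 h and -9.95 ± 0.64 (at least 226-fold) at 3 h. CRWN4 (AT5G65770) was lower by -5.56 ± 0.38 (at least 34.9-fold), -4.99 ± 0.38 (at least 18.8-fold) and -5.03 ± 0.38 (at least 19.9-fold, measured on 1 of 4 arrays). The largest limma adjusted p among these 9 differences was 3.1e-09. The CRWN1 probe was well above background on crwn1/4 replicates 3 and 4 at 0 h, where the 4 arrays read -6.93, -6.50, -1.75 and -2.13 (log2 relative to the array's 75th percentile). On replicates 3 and 4 CRWN4 was not well above background and the orphan gene QQS (AT3G30720) read -3.17 and -3.24, against -3.32 and -3.04 on the others and 3.70 to 4.23 in Col-0. Carry-over, a mixed sample and plants with CRWN1 transcript were not told apart as its source, so at 0 h CRWN1 checks the label of replicates 1 and 2 only. ATBCAT-5 (AT5G65780), an aminotransferase gene next to CRWN4, was lower in crwn1/4 at 0 h by -5.71 ± 0.27 (at least 20.7-fold). It was lower at 1 and 3 h (no size given).

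The response of wild-type roots to zeocin was taken first at 1 h against 0 h in Col-0. Of the DNA damage response (DDR) targets 17 of 22 rose and 0 fell (17 and 1 adjusted over the list alone). The median was 1.56, adjusted p = 1.7e-126. The largest rises in that list were those of SMR7 (AT3G27630, 4.81 ± 0.11) and SMR4 (AT5G02220, 3.28 ± 0.14), which encode inhibitors of cyclin-dependent kinases, the ribonucleotide reductase gene TSO2 (AT3G27060, 3.38 ± 0.11) and the thymidine kinase gene TK1A (AT3G07800, 3.26 ± 0.12). Outside the lists, AT5G07610 (5.82 ± 0.17), AT2G20970 (3.69 ± 0.86, at least 3.41-fold) and AT5G32594 (3.17 ± 0.83, at least 8.22-fold, measured on 3 of 4) rose most. The X-ray induced gene XRI1 (AT5G48720, 3.23 ± 0.10) rose. Of the heat shock genes 7 of 9 rose and 1 fell (8 and 1 adjusted over the list alone), among them HSP17.4 (AT3G46230, 2.45 ± 0.45), HSP90.1 (AT5G52640, 1.60 ± 0.30) and HSFA2 (AT2G26150, 1.43 ± 0.41). The median was 1.37, adjusted p = 0.021 and adjusted p = 0.73 with an estimated correlation. Of the G2/M mitotic genes 0 of 26 rose and 6 fell, among them the spindle gene TPX2 (AT1G03780, -0.63 ± 0.17) and the Aurora kinase gene AUR2 (AT2G25880, -0.52 ± 0.17). The median was -0.21, adjusted p = 0.0017 and adjusted p = 0.73 with an estimated correlation. The falls ranked first have bounds only (no 1 h array well above background): AT2G06400 (at least 1.38-fold), AtMT4b (AT2G23240, at least 1.55-fold), AT4G18540 (at least 1.32-fold), AT1G34620 (at least 1.105-fold), AT3G11110 (at least 1.13-fold), AT4G38781 (at least 1.302-fold), AT4G07946 (at least 1.49-fold) and AT4G14805 (at least 1.16-fold). All 8 lost the call with normexp (fitted changes -0.32 to -0.10).

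Limma called 6179 of 25122 genes (4057 higher, 2122 lower), and adjusted p was at most 0.028 for the 21 named. With normexp the split was 5544 higher and 1718 lower, and the median over all genes moved from 0.05 to 0.13. The count fell to 461 with slide and 532 with scan date and to 2719 on own arrays. Calls ended for AUR2 with quantile normalization and without slide 1, TPX2 and AUR2 in the series table and HSFA2, TPX2 and AUR2 on own arrays. Calls ended for 10 of the 21 with normexp, 15 with slide and 13 with scan date. AT2G20970 turned to -0.053 with slide and AT5G32594 to -0.62 with slide and -0.53 with scan date. Calls ended for AUR2 without Col-0 0 h rep 1, 2 or 4 or Col-0 1 h rep 1 or 2 (padj = 0.058 to 0.16) and HSFA2 without Col-0 0 h rep 4 (padj = 0.072). List calls ended for heat shock without Col-0 0 h rep 4 or Col-0 1 h rep 2 (padj = 0.052 to 0.096). The list test failed for G2/M with fry (padj = 0.071) and heat shock with slide (padj = 0.15).

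At 3 h against 0 h in Col-0, of the DDR targets 19 of 22 rose and 1 fell. The median was 4.57, adjusted p = 6.5e-262. SMR7 (7.73 ± 0.11), TK1A (7.18 ± 0.12), SMR5 (AT1G07500, 7.10 ± 0.12), TSO2 (6.51 ± 0.11) and SMR4 (6.51 ± 0.14) rose most in that list. Of the G2/M mitotic genes 0 of 26 rose and 24 fell (0 and 25 adjusted over the list alone), among them the cyclin genes CYCB2;2 (AT4G35620, -1.49 ± 0.16) and CYCB1;2 (AT5G06150, -1.17 ± 0.16), the microtubule gene EDE1 (AT2G44190, -1.29 ± 0.11) and TPX2 (-1.20 ± 0.17). The median was -0.80, adjusted p = 2.3e-10 and adjusted p = 0.13 with an estimated correlation. Of the heat shock genes 8 of 9 rose and 1 fell, with HSFA2 (3.40 ± 0.41), HSP17.4 (3.08 ± 0.45) and HSP17.6A (AT1G59860, 2.89 ± 0.40). The median was 2.45, adjusted p = 6.7e-04 and adjusted p = 0.33 with an estimated correlation. Of the circadian clock genes 3 of 19 rose and 8 fell (4 and 8 adjusted over the list alone), with falls of CCA1 (AT2G46830, -3.14 ± 0.20), LNK2 (AT3G54500, -1.76 ± 0.23) and PRR9 (AT2G46790, -1.55 ± 0.16). The median was -0.36, adjusted p = 0.025 and adjusted p = 0.18 with an estimated correlation. Harvest times of day were not given in the sources used here.

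Outside these lists the largest rises at 3 h were those of AT5G07610 (9.17 ± 0.17), AT4G25330 (8.95 ± 0.33, at least 235-fold), AT4G05380 (7.77 ± 0.36, at least 79.6-fold), WRKY50 (AT5G26170, 7.69 ± 0.09), AT5G60250 (7.40 ± 0.23, at least 116-fold, measured on 2 of 4) and GEX1 (AT5G55490, 7.37 ± 0.15). The largest falls were those of UMAMIT14 (AT2G39510, -5.54 ± 0.32, at least 11.2-fold), an amino acid exporter gene, AT5G62360 (-4.02 ± 0.12) and AT3G44870 (-3.80 ± 0.71, at least 3.20-fold), LHCB2.1 (AT2G05100, -3.80 ± 0.46, at least 12.4-fold, measured on 3 of 4) of the light-harvesting complex, the expansin gene EXPB3 (AT4G28250, -3.44 ± 0.23), the tyrosine aminotransferase gene TAT3 (AT2G24850, -3.32 ± 0.50, at least 8.45-fold, measured on 1 of 4), and BGLU24 (AT5G28510, -3.30 ± 0.23) and AT4G22214 (-3.24 ± 0.18). The other 15 lists did not pass the list test. For those described in no other comparison, rises and falls (and those adjusted over the list alone) were 8 and 1 of 21 in DNA repair (10 and 1), 3 and 8 of 22 in DNA replication, 6 and 5 of 22 in jasmonate, 1 and 1 of 7 in root hair markers, 1 and 3 of 8 in endodermis and 1 and 3 of 8 in photosynthetic shoot.

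Limma called 10344 genes (5644 higher, 4700 lower), and adjusted p was at most 7.0e-05 for the 29 named. With normexp the split was 7606 higher and 3602 lower, and the median over all genes moved from 0.01 to 0.13. The count was 4417 with slide and 4698 with scan date. Calls ended for TAT3 with slide. No scan day held Col-0 arrays of both times, so these terms rest on the 3 h arrays of the mutants scanned with the 0 h arrays.

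The step from 1 to 3 h in Col-0 set apart later changes on arrays that shared slides. GMI1 (AT5G24280, 4.89 ± 0.17), a gamma-irradiation induced gene, and SMR5 (4.59 ± 0.12) rose most among the DDR targets, of which 19 of 22 rose and 1 fell. The median was 3.01, adjusted p = 1.6e-188. AT4G25330 (7.38 ± 0.33, at least 107.4-fold) and AT4G05380 (6.06 ± 0.36, at least 31.4-fold, measured on 1 of 4) rose, and UMAMIT14 (-4.20 ± 0.32, at least 4.42-fold) and AT5G62360 (-3.79 ± 0.12) fell. The clock genes CCA1 (-1.78 ± 0.20) and PRR7 (AT5G02810, -1.28 ± 0.14) fell, and of the list 1 of 19 rose and 7 fell. The median was -0.30, adjusted p = 9.7e-04. The DNA repair, salicylic acid and heat shock lists passed as upward and the G2/M and stele lists as downward, adjusted p = 0.11 to 0.25 with an estimated correlation. Limma called 4910 genes (2309 higher, 2601 lower), and adjusted p was at most 5.3e-08 for the 8 named. Within slides and scan days, medians were 2.61 to 3.34 for the DDR and -1.02 to -0.35 for G2/M. The count was 2708 on own arrays.

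**Figure D2:**
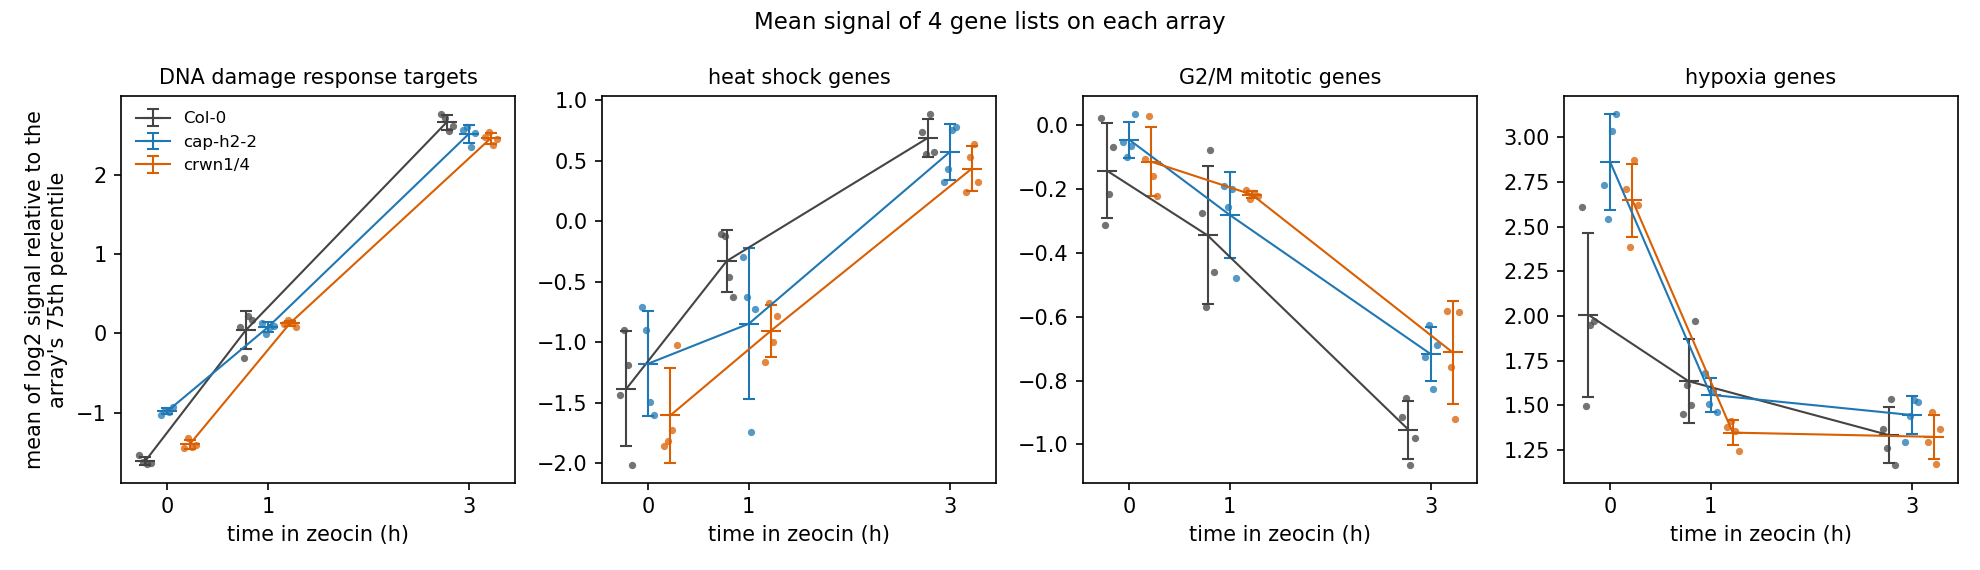
Mean log2 signal of 4 gene lists relative to the array's 75th percentile (vertical) against hours in zeocin (horizontal). Points are arrays and marks with bars are means ± SD (n = 4). The DDR targets rose from 0 to 3 h in each genotype, and the hypoxia genes were highest in both mutants at 0 h.

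Within cap-h2-2 at 1 h against 0 h, SMR7 (3.22 ± 0.11), SMR4 (2.68 ± 0.14) and TK1A (2.68 ± 0.12) rose, and of the DDR targets 16 of 22 rose and 2 fell. The median was 0.97, adjusted p = 8.3e-44. AT5G07610 (4.97 ± 0.17) and AT2G25890 (3.72 ± 0.69, at least 7.91-fold, measured on 1 of 4) were the largest rises outside the list, and AT4G01390 (-4.18 ± 0.43, at least 4.23-fold) and AT1G12805 (-3.88 ± 0.89, at least 9.74-fold, measured on 2 of 4) the largest falls. Of the hypoxia genes 0 of 14 rose and 10 fell (1 and 10 adjusted over the list alone), with falls of HRA1 (AT3G10040, -2.85 ± 0.38), a hypoxia-response attenuator gene, and PCO2 (AT5G39890, -2.51 ± 0.45, at least 5.68-fold, measured on 3 of 4), a cysteine oxidase gene. The median was -1.45, adjusted p = 1.4e-08 and adjusted p = 0.11 with an estimated correlation. The copper list passed as upward and the G2/M and stele lists as downward, adjusted p = 0.14 to 0.72 with an estimated correlation. Limma called 8517 genes (4536 higher, 3981 lower), and adjusted p was at most 0.0013 for the 9 named. The count was 3560 with slide and 2415 with scan date. Calls ended for AT2G25890, AT1G12805 and PCO2 with slide and with scan date. AT2G25890 turned to -0.36 with slide.

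At 3 h in cap-h2-2, TK1A (6.48 ± 0.12), SMR7 (5.94 ± 0.11) and SMR4 (5.64 ± 0.14) rose, and of the DDR targets 19 of 22 rose and 1 fell. The median was 3.57, adjusted p = 7.2e-181. The heat shock genes HSP17.4 (3.57 ± 0.45) and HSFA2 (2.99 ± 0.41) rose, and of the list 8 of 9 rose and 1 fell. The median was 1.86, adjusted p = 0.0026 and adjusted p = 0.26 with an estimated correlation. PCO2 (-2.82 ± 0.45, at least 6.01-fold, measured on 3 of 4) and the sucrose synthase gene SUS4 (AT3G43190, -2.69 ± 0.34) fell, and of the hypoxia genes 0 of 14 rose and 11 fell (0 and 12 adjusted over the list alone). The median was -1.46, adjusted p = 2.1e-05 and adjusted p = 0.095 with an estimated correlation. CCA1 (-2.62 ± 0.20) and LHY (AT1G01060, -2.23 ± 0.26, at least 3.84-fold, measured on 2 of 4) fell, and of the clock genes 5 of 19 rose and 12 fell. The median was -0.80, adjusted p = 3.8e-04 and adjusted p = 0.067 with an estimated correlation. The receptor kinase gene IMK2 (AT3G51740, -1.53 ± 0.21) and the kinesin gene HINKEL (AT1G18370, -1.48 ± 0.18) fell, and of the G2/M genes 1 of 26 rose and 21 fell. The median was -0.72, adjusted p = 5.4e-06 and adjusted p = 0.22 with an estimated correlation. The stele list passed as downward, adjusted p = 0.22 with an estimated correlation. Over all genes, AT5G07610 (8.29 ± 0.17) and AT4G25330 (7.30 ± 0.33, at least 140-fold, measured on 2 of 4) rose and LHCB2.1 (-5.77 ± 0.46, at least 26.9-fold) and AT5G62360 (-4.95 ± 0.12) fell most. Limma called 11554 genes (5800 higher, 5754 lower), and adjusted p was at most 8.6e-06 for the 15 named. Medians within slides and scan days were 3.47 to 3.503 for the DDR, -0.77 to -0.76 for G2/M and -1.49 to -1.31 for hypoxia. The count was 7467 with slide. Calls ended for LHY in the series table.

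From 1 to 3 h in cap-h2-2, AT4G25330 (6.56 ± 0.33, at least 86.6-fold, measured on 3 of 4) and EC1.3 (AT2G21750, 5.25 ± 0.37, at least 8.60-fold) rose and UMAMIT14 (-4.44 ± 0.32, at least 13.0-fold, measured on 1 of 4) and AT5G62360 (-3.34 ± 0.12) fell most. Of the DDR targets 19 of 22 rose and 0 fell. The median was 2.60, adjusted p = 3.9e-180. Of the clock genes 0 of 19 rose and 7 fell (2 and 9 adjusted over the list alone). The median was -0.35, adjusted p = 3.2e-04. The DNA repair and heat shock lists passed as upward and the G2/M and endodermis lists as downward, adjusted p = 0.19 to 0.46 with an estimated correlation. Limma called 4613 genes (2451 higher, 2162 lower), and adjusted p was at most 4.2e-12 for the 4 named. Within slides and scan days, medians were 2.46 to 2.79 for the DDR and -0.73 to -0.49 for G2/M. The count was 2500 on own arrays.

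In crwn1/4 at 1 h against 0 h, SMR7 (4.26 ± 0.11), SMR4 (3.28 ± 0.14) and XRI1 (3.22 ± 0.10) rose, and of the DDR targets 17 of 22 rose and 1 fell (17 and 2 adjusted over the list alone). The median was 1.48, adjusted p = 1.9e-70. AT5G07610 (5.08 ± 0.17) and the chaperone gene BIP3 (AT1G09080, 4.38 ± 0.47) were the largest rises outside the list, and AT1G12805 (-3.88 ± 0.89, at least 7.17-fold, measured on 1 of 4) and TAT3 (-3.83 ± 0.50) the largest falls. PCO2 (-3.45 ± 0.45, at least 5.93-fold) and HRA1 (-2.72 ± 0.38) fell, and of the hypoxia genes 1 of 14 rose and 11 fell. The median was -1.29, adjusted p = 8.0e-07 and adjusted p = 0.14 with an estimated correlation. The copper list passed as upward, adjusted p = 0.14 with an estimated correlation. Limma called 10922 genes (5997 higher, 4925 lower), and adjusted p was at most 0.0010 for the 9 named. With normexp the split was 5244 higher and 2681 lower. The count was 2677 with slide and 2774 with scan date. Calls ended for AT1G12805 and TAT3 with slide and AT1G12805 with scan date.

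At 3 h in crwn1/4, SMR7 (6.86 ± 0.11), TK1A (6.27 ± 0.12) and SMR4 (6.14 ± 0.14) rose, and of the DDR targets 19 of 22 rose and 1 fell. The median was 3.94, adjusted p = 2.1e-237. HSP17.4 (3.34 ± 0.45) and HSFA2 (3.32 ± 0.41) rose, and of the heat shock genes 8 of 9 rose and 0 fell. The median was 2.15, adjusted p = 1.0e-04 and adjusted p = 0.18 with an estimated correlation. PCO2 (-2.71 ± 0.45, at least 4.93-fold, measured on 2 of 4) and HRA1 (-2.33 ± 0.38) fell, and of the hypoxia genes 1 of 14 rose and 10 fell (1 and 12 adjusted over the list alone). The median was -1.52, adjusted p = 6.8e-05 and adjusted p = 0.16 with an estimated correlation. CCA1 (-3.35 ± 0.20) and LNK2 (-2.36 ± 0.23) fell, and of the clock genes 7 of 19 rose and 10 fell. The median was -0.38, adjusted p = 0.0060 and adjusted p = 0.16 with an estimated correlation. IMK2 (-1.52 ± 0.23) and EDE1 (-1.100 ± 0.11) fell, and of the G2/M genes 0 of 26 rose and 20 fell. The median was -0.64, adjusted p = 9.2e-06 and adjusted p = 0.19 with an estimated correlation. Over all genes, AT5G07610 (8.12 ± 0.17) and AT4G05380 (7.28 ± 0.36, at least 43.1-fold) rose and TAT3 (-6.28 ± 0.50, at least 29.7-fold, measured on 1 of 4) and UMAMIT14 (-5.66 ± 0.32, at least 19.0-fold) fell most. Limma called 10535 genes (5430 higher, 5105 lower), and adjusted p was at most 1.8e-05 for the 15 named. On the scan day that held both groups, medians were 4.16 for the DDR, -0.50 for G2/M and -1.36 for hypoxia. The count was 5072 with slide and 6297 with scan date. Calls ended for IMK2 in the series table.

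From 1 to 3 h in crwn1/4, AT4G25330 (6.75 ± 0.33, at least 96.9-fold) and the receptor-like kinase gene CRK6 (AT4G23140, 5.47 ± 0.37, at least 11.0-fold) rose and UMAMIT14 (-5.46 ± 0.32, at least 16.5-fold) and LHCB2.1 (-2.97 ± 0.46, at least 6.68-fold, measured on 2 of 4) fell most. Of the DDR targets 19 of 22 rose and 0 fell. The median was 2.66, adjusted p = 1.9e-164. Of the clock genes 0 of 19 rose and 7 fell (1 and 7 adjusted over the list alone). The median was -0.28, adjusted p = 1.3e-04. The salicylic acid and heat shock lists passed as upward and the G2/M, endodermis and photosynthetic shoot lists as downward, adjusted p = 0.14 to 0.29 with an estimated correlation. Limma called 5095 genes (2296 higher, 2799 lower), and adjusted p was at most 1.4e-05 for the 4 named. Medians within slides and scan days were 2.57 to 2.74 for the DDR and -0.81 to -0.51 for G2/M.

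Across genotypes, 1660 genes rose and 769 fell at 1 h in all 3, and 3412 rose and 2427 fell at 3 h. The fold changes of different genotypes, which share no arrays, correlated across genes with r between 0.55 and 0.69 at 1 h and between 0.80 and 0.86 at 3 h, and genes are not independent. Independent lists of the sizes of Col-0 and cap-h2-2 at 3 h would share 1303 rises and 1076 falls, against 3700 and 2891 observed.

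Before zeocin, cap-h2-2 was compared with Col-0 at 0 h. Of the DDR targets 11 of 22 were higher and 0 lower (18 and 0 adjusted over the list alone). The median was 0.49, adjusted p = 2.2e-37. GMI1 (1.67 ± 0.17), SMR7 (1.60 ± 0.11) and SMR5 (1.38 ± 0.12) and the NAC factor gene ANAC044 (AT3G01600, 1.11 ± 0.11) were highest among them. Of the hypoxia genes 9 of 14 were higher and 0 lower (11 and 1 adjusted over the list alone), with PCO2 (2.11 ± 0.45), SUS4 (1.66 ± 0.34) and HRA1 (1.47 ± 0.38) and the alcohol dehydrogenase gene ADH1 (AT1G77120, 1.21 ± 0.31). The median was 0.84, adjusted p = 1.0e-09. The zinc transporter gene ZIP2 (AT5G59520, -1.55 ± 0.17) and the iron superoxide dismutase gene FSD1 (AT4G25100, -0.80 ± 0.17) were lower, and of the copper homeostasis genes 1 of 17 was higher and 2 lower (1 and 3 adjusted over the list alone). The median was -0.20, adjusted p = 0.0027 and adjusted p = 0.051 with an estimated correlation. Of the condensin subunits 0 of 9 were higher and 1 lower. The median was -0.02, adjusted p = 7.2e-09 and adjusted p = 0.28 with an estimated correlation. Of the DNA methylation and silencing genes 0 of 11 were higher and 1 lower. The median was 0.08, adjusted p = 6.1e-05 and adjusted p = 0.87 with an estimated correlation. Called were CAP-H2 and QQS, and the list means were -0.59 and -0.50. The DNA replication list passed as higher and the iron and photosynthetic shoot lists as lower, adjusted p = 0.061 to 0.59 with an estimated correlation. Without CAP-H2 and QQS, the condensin and DNA methylation lists did not pass (padj = 0.54 and 0.37).

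Over all genes, QQS (AT3G30720, -6.64 ± 0.22), an orphan gene, CAP-H2, AT5G03090 (-4.15 ± 0.71, at least 14.0-fold, measured on 3 of 4) and MRD1 (AT1G53480, -4.03 ± 0.86), AT2G36255 (-2.52 ± 0.48), the microRNA gene MIR398a (AT2G03445, -1.96 ± 0.29), and AT1G34047 (-1.83 ± 0.19) and AT3G11110 (-1.73 ± 0.37, at least 1.83-fold) were lower in cap-h2-2 at 0 h. AT5G60250 (3.98 ± 0.23, at least 10.8-fold, measured on 2 of 4) and AT4G33720 (3.12 ± 0.36), the transporter gene ABCA10 (AT5G61740, 2.86 ± 0.32, at least 5.23-fold, measured on 1 of 4), AT5G55270 (2.50 ± 0.43, at least 4.92-fold, measured on 3 of 4), AT2G47780 (2.48 ± 0.59) and AT5G09570 (2.42 ± 0.29) and the MADS-box gene AGL72 (AT5G51860, 1.96 ± 0.35, at least 3.75-fold, measured on 2 of 4) were higher. Limma called 786 genes (531 higher, 255 lower), and adjusted p was at most 0.026 for the 25 named. Within slides and scan days, medians were 0.37 to 0.59 for the DDR. The hypoxia median was 0.08 on slide 6, 1.09 on slide 7 and 1.18 on slide 8. The count was 1996 with slide and 1283 with scan date and changed without Col-0 rep 1 (1540), 2 (417), 3 (334) or 4 (411) or cap-h2-2 rep 1 (447), 2 (509), 3 (419) or 4 (393). Calls ended for PCO2 without Col-0 rep 2 (padj = 0.0504), HRA1 and ADH1 without Col-0 rep 2, 3 or 4 or cap-h2-2 rep 3 or 4 (padj = 0.063 to 0.15) and AT2G47780 without cap-h2-2 rep 1 or 3 (padj = 0.052 to 0.055). Calls ended for AT3G11110 with normexp, AT2G47780 with quantile normalization and in the series table and 6 of the 25 on own arrays.

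At 1 h in cap-h2-2 against Col-0, the xylem regulator gene VND7 (AT1G71930, -0.70 ± 0.11), the secondary wall cellulose synthase gene CESA8 (AT4G18780, -0.67 ± 0.13) and the phloem sucrose transporter gene SUC2 (AT1G22710, -0.54 ± 0.12) were lower, and of the stele and vascular markers 0 of 9 were higher and 5 lower (0 and 6 adjusted over the list alone). The median was -0.39, adjusted p = 4.6e-04 and adjusted p = 0.12 with an estimated correlation. PBS3 (AT5G13320, 1.39 ± 0.34) and CBP60G (AT5G26920, 1.03 ± 0.28), which act in salicylic acid synthesis, and WRKY46 (AT2G46400, 1.01 ± 0.25) were higher, and of the salicylic acid and immune genes 5 of 18 were higher and 0 lower. The median was 0.35, adjusted p = 0.0029 and adjusted p = 0.12 with an estimated correlation. AT4G33720 (3.15 ± 0.36) and AT5G60250 (3.06 ± 0.23, at least 8.35-fold, measured on 3 of 4) were higher and QQS (-6.36 ± 0.22) and MRD1 (-5.99 ± 0.86) lower by most. The condensin, clock, iron and DNA methylation lists passed as lower, adjusted p = 0.12 to 0.76 with an estimated correlation. Without CAP-H2 and QQS, the condensin and DNA methylation lists did not pass (padj = 0.84). Limma called 2459 genes (955 higher, 1504 lower), and adjusted p was at most 0.019 for the 10 named. Medians within slides and scan days were -0.59 to -0.09 for stele and 0.10 to 0.50 for salicylic acid. The count was 4136 with slide, 113 on own arrays and changed without cap-h2-2 rep 1 (3780), 2 (1339) or 3 (1375). Calls ended for CBP60G without Col-0 rep 3 or cap-h2-2 rep 2 (padj = 0.078 to 0.093) and WRKY46 without cap-h2-2 rep 2 (padj = 0.065). Calls ended for SUC2 in the series table and CESA8, SUC2, PBS3, CBP60G and WRKY46 on own arrays.

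At 3 h, the cohesin gene SYN2 (AT5G40840, -0.69 ± 0.18) and SMR5 (-0.55 ± 0.12) and SMR4 (-0.44 ± 0.14) were lower in cap-h2-2 than in Col-0, and of the DDR targets 0 of 22 were higher and 3 lower. The median was -0.16, adjusted p = 0.021 and adjusted p = 0.49 with an estimated correlation. The G2/M genes CYCB2;2 (0.72 ± 0.16), CDKB2;2 (AT1G20930, 0.45 ± 0.11) and AUR1 (AT4G32830, 0.41 ± 0.12) were higher, and of the list 6 of 26 were higher and 0 lower (14 and 0 adjusted over the list alone). The median was 0.24, adjusted p = 9.1e-06 and adjusted p = 0.41 with an estimated correlation. The root cap factor genes SMB (AT1G79580, 0.88 ± 0.15) and BRN1 (AT1G33280, 0.67 ± 0.10) were higher, and of the root tip markers 2 of 6 were higher and 0 lower (3 and 0 adjusted over the list alone). The median was 0.52, adjusted p = 9.6e-04 and adjusted p = 0.11 with an estimated correlation. AT5G09570 (2.55 ± 0.29, at least 4.40-fold) and AT2G47780 (2.44 ± 0.59, at least 2.33-fold, measured on 1 of 4) were higher and QQS (-6.30 ± 0.22) and MRD1 (-5.74 ± 0.86) lower by most. The DNA replication list passed as higher and the DNA repair, condensin, clock, DNA methylation and stele lists as lower, adjusted p = 0.22 to 0.71 with an estimated correlation. Without CAP-H2 and QQS, the condensin and DNA methylation lists did not pass (padj = 0.58 and 0.98).

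In cap-h2-2 at 3 h limma called 2183 genes (1135 higher, 1048 lower), and adjusted p was at most 0.038 for the 12 named. Within slides and scan days, medians were -0.24 to -0.10 for the DDR and 0.21 to 0.26 for G2/M. The count was 156 on own arrays, 1341 without the 3 h arrays of scan day 4 (cap-h2-2 and crwn1/4 rep 4) and changed without Col-0 rep 1 (889) or 3 (1373) or cap-h2-2 rep 2 (1357), 3 (1163) or 4 (1454). Calls ended for SYN2 without Col-0 rep 1 or 3 or cap-h2-2 rep 3 (padj = 0.075 to 0.091), SMR4 without any array but cap-h2-2 rep 1 (padj = 0.0505 to 0.11) and CDKB2;2 without Col-0 rep 1 or cap-h2-2 rep 2 (padj = 0.0504 to 0.062). Calls ended for AUR1 without Col-0 rep 1, 3 or 4 or cap-h2-2 rep 2 or 3 (padj = 0.070 to 0.14). List calls ended for DDR without Col-0 rep 2 or cap-h2-2 rep 3 (padj = 0.060 to 0.092). Calls ended for SMR4 with quantile normalization, with scan date and without the 3 h arrays of scan day 4, SMR4 and AUR1 unfiltered and SYN2 and SMR4 with slide. Calls ended for 8 of the 12 on own arrays. The list test failed for DDR with fry, with normexp or with slide (padj = 0.060 to 0.080).

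Before zeocin, crwn1/4 was compared with Col-0 at 0 h. SMR5 (0.70 ± 0.12), TK1A (0.64 ± 0.12) and GMI1 (0.63 ± 0.17) were higher, and of the DDR targets 4 of 22 were higher and 0 lower (6 and 0 adjusted over the list alone). The median was 0.19, adjusted p = 3.1e-04 and adjusted p = 0.28 with an estimated correlation. PCO2 (1.66 ± 0.45), SUS4 (1.27 ± 0.34) and PCO1 (AT5G15120, 0.91 ± 0.24) were higher, and of the hypoxia genes 4 of 14 were higher and 0 lower (7 and 0 adjusted over the list alone). The median was 0.57, adjusted p = 3.1e-04 and adjusted p = 0.23 with an estimated correlation. The metal genes ZIP2 (-1.68 ± 0.17) and MT2A (AT3G09390, -0.78 ± 0.22), a metallothionein gene, were lower, and of the copper genes 0 of 17 were higher and 3 lower (0 and 4 adjusted over the list alone). The median was -0.20, adjusted p = 0.0025 and adjusted p = 0.074 with an estimated correlation. IMA1 (AT1G47400, -1.40 ± 0.32) and FIT (AT2G28160, -0.91 ± 0.12), regulators of iron uptake, were lower, and of the iron deficiency genes 0 of 13 were higher and 3 lower (0 and 4 adjusted over the list alone). The median was -0.24, adjusted p = 0.0019 and adjusted p = 0.074 with an estimated correlation. Of the nuclear lamina and LINC complex genes 0 of 19 were higher and 2 lower. The median was 0.02, adjusted p = 0.014 and adjusted p = 0.69 with an estimated correlation. The mean of that list was -0.66. The DNA methylation, endodermis and root tip lists passed as lower, adjusted p = 0.18 to 0.69 with an estimated correlation. Without CRWN1, CRWN4 and QQS, the lamina and LINC and DNA methylation lists did not pass (padj = 0.71 and 0.63).

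Over all genes, CRWN1, QQS (-7.24 ± 0.22), ATBCAT-5, CRWN4, MRD1 (-4.33 ± 0.86), AT5G03090 (-4.30 ± 0.71), AT2G36255 (-3.60 ± 0.48) and AT1G34047 (-2.51 ± 0.19) were lower by most in crwn1/4 at 0 h. AT3G42930 (5.16 ± 0.41), AT2G43890 (3.00 ± 0.46, at least 7.49-fold, measured on 3 of 4) and AT4G04100 (2.95 ± 0.23), the phosphate transporter gene PHT1;3 (AT5G43360, 2.15 ± 0.46, at least 2.49-fold, measured on 2 of 4), CYP96A11 (AT4G39500, 2.102 ± 0.43), AT1G63530 (2.04 ± 0.13) and WRKY30 (AT5G24110, 1.96 ± 0.51, at least 3.36-fold, measured on 3 of 4) and the cell wall gene XTH26 (AT4G28850, 1.96 ± 0.34) were higher by most. Limma called 1002 genes (339 higher, 663 lower), and adjusted p was at most 0.035 for the 26 named. With normexp the split was 699 higher and 730 lower. Medians within slides and scan days were 0.17 to 0.25 for the DDR and 0.57 to 0.81 for hypoxia. The count was 2964 with slide, 1583 with scan date, 656 on own arrays and changed without Col-0 rep 1 (1855), 2 (649), 3 (397) or 4 (542) or crwn1/4 rep 1 (504) or 2 (474).

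Calls ended for GMI1 without Col-0 rep 2, 3 or 4 or crwn1/4 rep 2 or 4 (padj = 0.058 to 0.17), PCO2 without any array but Col-0 rep 1 and crwn1/4 rep 2 (padj = 0.055 to 0.16) and SUS4 and PCO1 without Col-0 rep 2, 3 or 4 or crwn1/4 rep 1 or 3 (padj = 0.058 to 0.15). Calls ended for MT2A without any array but Col-0 rep 1 and crwn1/4 rep 4 (padj = 0.052 to 0.17), IMA1 without Col-0 rep 3 or crwn1/4 rep 1 (padj = 0.052 to 0.060) and WRKY30 without Col-0 rep 4 or crwn1/4 rep 2 or 4 (padj = 0.053 to 0.11). List calls ended for lamina and LINC without Col-0 rep 1 (padj = 0.083). Calls ended for GMI1 with normexp, PHT1;3, WRKY30, GMI1, PCO2 and MT2A with quantile normalization and PHT1;3, CYP96A11, TK1A and GMI1 in the series table. Calls ended for 9 of the 26 on own arrays and 6 without crwn1/4 0 h rep 3 and 4. The list test failed for lamina and LINC with slide (padj = 0.062).

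At 1 h, CRWN1 and QQS (-7.55 ± 0.22, at least 177-fold, measured on 3 of 4) were lower and AT3G42930 (5.44 ± 0.41, at least 22.4-fold) and AT4G04100 (3.82 ± 0.23, at least 13.8-fold, measured on 1 of 4) higher by most in crwn1/4. The G2/M list passed as higher and the jasmonate and DNA methylation lists as lower, adjusted p = 0.71 to 0.91 with an estimated correlation. Without QQS, the DNA methylation list did not pass (padj = 0.22). Limma called 1574 genes (576 higher, 998 lower), and adjusted p was at most 1.7e-10 for the 4 named. With quantile normalization the split was 755 higher and 822 lower. Within slides and scan days, medians were -0.07 to 0.36 for G2/M. The count was 223 on own arrays and changed without Col-0 rep 1 (1048) or crwn1/4 rep 3 (1004).

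At 3 h, SMR4 (-0.65 ± 0.14), SYN2 (-0.62 ± 0.18) and SMR5 (-0.55 ± 0.12) were lower in crwn1/4 than in Col-0, and of the DDR targets 0 of 22 were higher and 7 lower (1 and 10 adjusted over the list alone). The median was -0.27, adjusted p = 4.5e-04 and adjusted p = 0.41 with an estimated correlation. The root cap factor genes BRN2 (AT4G10350, 0.56 ± 0.15), SMB (0.50 ± 0.15) and BRN1 (0.35 ± 0.10) were higher, and of the root tip markers 3 of 6 were higher and 0 lower. The median was 0.42, adjusted p = 0.0035 and adjusted p = 0.14 with an estimated correlation. CYCB2;2 (0.56 ± 0.16) and the kinesin gene PAKRP1 (AT4G14150, 0.44 ± 0.13) were higher, and of the G2/M genes 3 of 26 were higher and 0 lower. The median was 0.22, adjusted p = 1.6e-05 and adjusted p = 0.41 with an estimated correlation. AT3G42930 (5.55 ± 0.41, at least 21.0-fold, measured on 1 of 4) and AT4G04100 (4.07 ± 0.23, at least 16.7-fold, measured on 2 of 4) were higher and CRWN1 and QQS (-7.39 ± 0.22) lower by most. The DNA replication list passed as higher and the lamina and LINC and DNA methylation lists as lower, adjusted p = 0.41 to 0.69 with an estimated correlation. Without CRWN1, CRWN4 and QQS, the lamina and LINC and DNA methylation lists did not pass (padj = 0.90 and 0.84).

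In crwn1/4 at 3 h limma called 2250 genes (755 higher, 1495 lower), and adjusted p was at most 0.033 for the 12 named. Medians within slides and scan days were -0.34 to -0.25 for the DDR and 0.05 to 0.31 for G2/M. The count was 801 on own arrays, 1186 without the 3 h arrays of scan day 4 and changed without Col-0 rep 1 (1191) or crwn1/4 rep 4 (1191). Calls ended for SYN2 without Col-0 rep 1 or 3 or crwn1/4 rep 3 or 4 (padj = 0.074 to 0.12), SMB, CYCB2;2 and PAKRP1 without Col-0 rep 1 or 3 or crwn1/4 rep 1 or 4 (padj = 0.057 to 0.17) and BRN1 without Col-0 rep 1 or 3 or crwn1/4 rep 1, 3 or 4 (padj = 0.057 to 0.094). Calls ended for BRN2 without crwn1/4 rep 2 (padj = 0.057). Calls ended for CYCB2;2 and PAKRP1 with normexp and in the series table, SMB and CYCB2;2 with quantile normalization and BRN1 and PAKRP1 with slide. Calls ended for SYN2, SMB and PAKRP1 with scan date, SYN2, SMB, BRN1, CYCB2;2 and PAKRP1 without the 3 h arrays of scan day 4 and 6 of the 12 on own arrays.

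Whether both mutants differ from Col-0 in the same genes at 0 h was asked with their fold changes, which correlated across genes with r = 0.53 (covariance 0.0540). Both comparisons use the same Col-0 arrays, and simulated unchanged groups with these in common gave r = 0.498 (covariance 0.0163) and 0 shared calls. With the Col-0 arrays split between the comparisons, r averaged 0.309 (covariance 0.0364). Both mutants were higher in 80 genes and lower in 119, where independent lists would share 7.17 and 6.73, and 3 genes went opposite ways. With split controls, an average of 13.8 genes were higher and 38.0 lower in both, against 1.09 and 1.22 for independent lists. The counts higher, lower and opposite were 305, 354 and 19 with slide as a term, where independent lists would share 48.2 and 60.02, and 148, 125 and 1 with normexp (19.6 and 7.85).

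Whether cap-h2-2 responds to zeocin otherwise than Col-0 was asked with the difference between their responses. At 1 h, the difference was negative for SMR7 (-1.59 ± 0.16), SMR5 (-1.39 ± 0.17) and TSO2 (-1.24 ± 0.16), and of the DDR targets 0 of 22 were positive and 11 negative (0 and 14 adjusted over the list alone). The median was -0.51, adjusted p = 2.5e-11 and adjusted p = 0.086 with an estimated correlation. It was negative for SUS4 (-1.89 ± 0.48), HRA1 (-1.75 ± 0.53) and ADH1 (-1.44 ± 0.44), and of the hypoxia genes 1 of 14 was positive and 8 negative (1 and 10 adjusted over the list alone). The median was -0.84, adjusted p = 2.2e-04 and adjusted p = 0.28 with an estimated correlation. It was negative for CESA8 (-1.0002 ± 0.19), CESA4 (AT5G44030, -0.998 ± 0.18) and SUC2 (-0.73 ± 0.17), and of the stele and vascular markers 0 of 9 were positive and 6 negative. The median was -0.63, adjusted p = 2.2e-04 and adjusted p = 0.086 with an estimated correlation. AT4G25580 (2.73 ± 0.67) headed the positive and AT2G30540 (-2.92 ± 0.68) the negative calls measured in each group. AT3G11110 (unmeasured in 3 groups) and the gibberellin 2-oxidase gene ATGA2OX1 (AT1G78440, unmeasured in 1 group) were also called, with no size given. Limma called 2947 genes (1133 higher, 1814 lower), and adjusted p was at most 0.031 for the 13 named. With normexp the median over all genes moved from -0.07 to -0.14. The count was 5121 with slide, 1232 on own arrays and changed without Col-0 0 h rep 2 (1798) or cap-h2-2 1 h rep 3 (1859). Calls ended for HRA1 without Col-0 0 h rep 2 or 3, cap-h2-2 0 h rep 3 or 4, Col-0 1 h rep 3 or 4 or cap-h2-2 1 h rep 2 or 3 (padj = 0.051 to 0.091) and ADH1 without Col-0 0 h rep 2, 3 or 4, cap-h2-2 0 h rep 3 or 4, Col-0 1 h rep 4 or cap-h2-2 1 h rep 2 or 4 (padj = 0.052 to 0.093). Calls ended for AT3G11110 with normexp, SUC2 and ADH1 in the series table and 6 of the 13 on own arrays.

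At 3 h, the difference between cap-h2-2 and Col-0 was negative for GMI1 (-2.001 ± 0.25), SMR5 (-1.93 ± 0.17), SMR7 (-1.79 ± 0.16) and SYN2 (-1.28 ± 0.26), and of the DDR targets 0 of 22 were positive and 15 negative (0 and 17 adjusted over the list alone). The median was -0.65, adjusted p = 9.5e-21. It was negative for SUS4 (-1.69 ± 0.48) and the NADPH oxidase gene RBOHD (AT5G47910, -0.91 ± 0.24), and of the hypoxia genes 1 of 14 was positive and 5 negative (1 and 10 adjusted over the list alone). The median was -0.83, adjusted p = 0.0018 and adjusted p = 0.32 with an estimated correlation. It was positive for SMB (1.31 ± 0.21) and BRN1 (0.57 ± 0.15), and of the root tip markers 2 of 6 were positive and 0 negative (3 and 0 adjusted over the list alone). The median was 0.58, adjusted p = 0.0052 and adjusted p = 0.11 with an estimated correlation. It was positive for CYCB2;2 (0.75 ± 0.22) and CDKB2;2 (0.56 ± 0.16), and of the G2/M genes 5 of 26 were positive and 0 negative. The median was 0.15, adjusted p = 0.014 and adjusted p = 0.68 with an estimated correlation. AT2G42560 (3.38 ± 0.85) headed the positive and AT5G60250 (-3.10 ± 0.33) and AT5G03480 (-2.77 ± 0.80) the negative calls measured in each group. The ferric reductase gene FRO1 (AT1G01590, unmeasured in 3 groups) was also called. The DNA repair, salicylic acid and stele lists passed as negative, adjusted p = 0.24 to 0.40 with an estimated correlation.

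Here limma called 2708 genes (1204 higher, 1504 lower), and adjusted p was at most 0.043 for the 14 named. With normexp the median over all genes moved from -0.06 to -0.14. The count was 4130 with slide and changed without Col-0 0 h rep 2 (1723), Col-0 3 h rep 1 (1413) or cap-h2-2 3 h rep 3 (1744). Calls ended for SUS4 without Col-0 0 h rep 2 or cap-h2-2 0 h rep 3 or 4 (padj = 0.052 to 0.063), CDKB2;2 without Col-0 0 h rep 2, Col-0 3 h rep 1 or cap-h2-2 3 h rep 2 (padj = 0.054 to 0.058) and FRO1 without any array but Col-0 0 h rep 1 and 2, cap-h2-2 0 h rep 2, 3 and 4 and cap-h2-2 3 h rep 2 (padj = 0.0502 to 0.11). Calls ended for CYCB2;2 without Col-0 0 h rep 4, cap-h2-2 0 h rep 2, 3 or 4, Col-0 3 h rep 1 or 3 or cap-h2-2 3 h rep 2 or 3 (padj = 0.052 to 0.076) and AT5G03480 without Col-0 3 h rep 4 or cap-h2-2 3 h rep 3 (padj = 0.052 to 0.060). List calls ended for G2/M without Col-0 0 h rep 1 (padj = 0.11). Calls ended for AT2G42560, FRO1 and CYCB2;2 with normexp, FRO1 unfiltered and without the 3 h arrays of scan day 4 and SUS4 on own arrays. The list test failed for G2/M with fry (padj = 0.33).

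The same difference between crwn1/4 and Col-0 at 1 h was negative for the hypoxia genes HRE2 (AT2G47520, -2.13 ± 0.58) and LBD41 (AT3G02550, -0.95 ± 0.24), and of that list 0 of 14 were positive and 2 negative (1 and 10 adjusted over the list alone). The median was -0.94, adjusted p = 8.5e-05 and adjusted p = 0.29 with an estimated correlation. The defensin gene PDF2.1 (AT2G02120, 1.74 ± 0.40) headed the positive calls measured in each group. AT2G25625 (unmeasured in 2 groups), AT2G24910 (unmeasured in 1 group) and AT1G55230 (unmeasured in 2 groups) were also called. The endodermis and root tip lists passed as positive and the jasmonate list as negative, adjusted p = 0.29 to 0.77 with an estimated correlation. Limma called 782 genes (236 higher, 546 lower), and adjusted p was at most 0.042 for the 6 named. The split was 251 higher and 303 lower with quantile normalization and 179 higher and 239 lower in the series table. The count was 1386 with normexp, 1187 with slide, 450 with scan date, 291 on own arrays, 474 without slide 1 and 235 without crwn1/4 0 h rep 3 and 4. It changed without Col-0 0 h rep 1 (1511), 2 (170), 3 (298) or 4 (403), crwn1/4 0 h rep 2 (245) or 3 (282), Col-0 1 h rep 1 (304), 2 (1689) or 4 (313) or crwn1/4 1 h rep 1 (377) or 3 (234).

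Calls ended for AT2G25625 without Col-0 0 h rep 2, 3 or 4, crwn1/4 0 h rep 2 or 3, Col-0 1 h rep 1 or 3 or crwn1/4 1 h rep 3 (padj = 0.056 to 0.091), PDF2.1 without Col-0 0 h rep 2 or crwn1/4 1 h rep 3 (padj = 0.055 to 0.056) and AT2G24910 without Col-0 0 h rep 2, crwn1/4 0 h rep 2 or 3 or crwn1/4 1 h rep 1 (padj = 0.0501 to 0.060). Calls ended for HRE2 without Col-0 0 h rep 2, 3 or 4, crwn1/4 0 h rep 1, 3 or 4, Col-0 1 h rep 1 or crwn1/4 1 h rep 1 or 3 (padj = 0.054 to 0.093), LBD41 without Col-0 0 h rep 2, 3 or 4, crwn1/4 0 h rep 3, Col-0 1 h rep 4 or crwn1/4 1 h rep 1 or 3 (padj = 0.051 to 0.088) and AT1G55230 without Col-0 0 h rep 4 (padj = 0.052). Calls ended for AT2G25625 with normexp, AT2G24910 and AT1G55230 with quantile normalization and in the series table and HRE2 unfiltered and with slide. Calls ended for AT2G25625 and HRE2 with scan date and without slide 1, 5 of the 6 on own arrays and 6 of the 6 without crwn1/4 0 h rep 3 and 4.

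At 3 h, the difference between crwn1/4 and Col-0 was negative for SMR5 (-1.25 ± 0.17), TK1A (-0.91 ± 0.17) and SMR7 (-0.87 ± 0.16), and of the DDR targets 0 of 22 were positive and 5 negative (0 and 11 adjusted over the list alone). The median was -0.41, adjusted p = 1.8e-11. It was positive for BRN2 (1.00 ± 0.21) and BRN1 (0.62 ± 0.15), and of the root tip markers 2 of 6 were positive and 0 negative (3 and 0 adjusted over the list alone). The median was 0.74, adjusted p = 1.4e-06. MIR398a (1.78 ± 0.41) and HVA22B (AT5G62490, 1.57 ± 0.31) headed the positive and TAT3 (-2.95 ± 0.70) the negative calls measured in each group. The cytochrome P450 gene CYP71B22 (AT3G26200, unmeasured in 1 group) was also called. The G2/M and DNA replication lists passed as positive and the jasmonate and hypoxia lists as negative, adjusted p = 0.29 to 0.62 with an estimated correlation. Limma called 123 genes (46 higher, 77 lower), and adjusted p was at most 0.047 for the 9 named. In the series table the split was 55 higher and 58 lower. The count was 618 with slide, 73 unfiltered, 19 on own arrays, 43 without the 3 h arrays of scan day 4 and 17 without crwn1/4 0 h rep 3 and 4. It changed without Col-0 0 h rep 1 (268), 3 (37) or 4 (49), crwn1/4 0 h rep 1 (71), 2 (55), 3 (46) or 4 (68), Col-0 3 h rep 1 (46) or 2 (233) or crwn1/4 3 h rep 1 (65), 3 (77) or 4 (43).

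Calls ended for TAT3 without any array but Col-0 0 h rep 2, Col-0 3 h rep 2 and crwn1/4 3 h rep 2 and 4 (padj = 0.051 to 0.12), MIR398a without any array but Col-0 0 h rep 1 and Col-0 3 h rep 2 and 3 (padj = 0.052 to 0.11) and HVA22B without Col-0 0 h rep 3 (padj = 0.060). Calls ended for CYP71B22 without Col-0 0 h rep 3 or 4, crwn1/4 0 h rep 1 or 4, Col-0 3 h rep 1 or 4 or crwn1/4 3 h rep 1 or 4 (padj = 0.051 to 0.065), BRN2 without Col-0 0 h rep 3 or 4 or crwn1/4 0 h rep 3 (padj = 0.054 to 0.065) and BRN1 without any array but Col-0 0 h rep 1 and 2 and Col-0 3 h rep 2 (padj = 0.055 to 0.12). Calls ended for MIR398a, TAT3 and BRN1 with normexp and unfiltered, CYP71B22, TK1A and SMR7 with quantile normalization and MIR398a, TK1A and SMR7 in the series table. Calls ended for MIR398a and BRN1 with scan date, MIR398a, CYP71B22 and BRN1 without the 3 h arrays of scan day 4 and 6 of the 9 on own arrays. Calls ended for 7 of the 9 without crwn1/4 0 h rep 3 and 4.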

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

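Chosen only after the result was seen were the tests of the direction of the 3 h changes and on proteasome genes. So were, for the DDR targets, those on the level before zeocin and on saturated spots. Single arrays stood apart by Dixon's ratio (gap to the nearest array over the range) for 34 of 438 genes in a group and 8 of 171 list means, where chance gives about 1 in 20. In Col-0 at 0 h they were replicate 1 for SUC2 (0.875), CRWN1 (0.938), CYP71B22 (0.842), LNK2 (0.843) and lamina and LINC (0.958), replicate 2 for AtMT4b (0.850), AT2G36255 (0.900) and AT5G55270 (0.853), replicate 3 for AT1G34620 (0.885) and replicate 4 for HSFA2 (0.850). In Col-0 at 1 h they were replicate 1 for PBS3 (0.841), replicate 2 for AT2G24910 (0.850) and QQS (0.833) and replicate 4 for PRR7 (0.895) and copper (0.884). In Col-0 at 3 h they were replicate 2 for CDKB2;2 (0.931) and replicate 3 for PAKRP1 (0.850) and AT5G60250 (0.866). In cap-h2-2 at 0 h they were replicate 1 for FRO1 (0.927), SMB (0.833), CYCB2;2 (0.893) and SMR4 (0.879) and replicate 3 for CESA8 (0.849). In cap-h2-2 at 1 h they were replicate 1 for SMR7 (0.873) and photosynthetic shoot (0.956) and replicate 2 for WRKY46 (0.879) and stele (0.858). In cap-h2-2 at 3 h they were replicate 1 for SMR5 (0.866) and MRD1 (0.835), replicate 2 for endodermis (0.853) and replicate 3 for PCO2 (0.893). In crwn1/4 at 0 h they were replicate 1 for PDF2.1 (0.912), replicate 2 for endodermis (0.881), replicate 3 for XRI1 (0.934) and replicate 4 for HSFA2 (0.883), WRKY30 (0.879) and heat shock (0.840). In crwn1/4 at 1 h they were replicate 4 for stele (0.948). In crwn1/4 at 3 h they were replicate 3 for LNK2 (0.886) and PCO2 (0.909) and replicate 4 for SMR5 (0.909) and SMR7 (0.919).

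Zeocin responses differed between a mutant and Col-0, by the test of the difference, in 2947 genes for cap-h2-2 at 1 h, 2708 at 3 h, 782 for crwn1/4 at 1 h and 123 at 3 h. List calls for cap-h2-2 at 1 h (medians) were DDR (-0.51), hypoxia (-0.84) and stele (-0.63), with adjusted p = 0.086 to 0.28 with an estimated correlation. List calls for cap-h2-2 at 3 h (medians) were DDR (-0.65), DNA repair (-0.24), G2/M (0.15), salicylic acid (-0.33), hypoxia (-0.83), stele (-0.28) and root tip (0.58), of which only DDR held (the others had adjusted p = 0.11 to 0.68 with an estimated correlation). List calls for crwn1/4 at 1 h (medians) were jasmonate (-0.40), hypoxia (-0.94), endodermis (0.27) and root tip (0.48), with adjusted p = 0.29 to 0.77 with an estimated correlation, and root tip had adjusted p = 0.062 with the replicate block. List calls for crwn1/4 at 3 h (medians) were DDR (-0.41), G2/M (0.23), DNA replication (0.22), jasmonate (-0.34), hypoxia (-0.73) and root tip (0.74), of which only DDR and root tip held (the others had adjusted p = 0.29 to 0.62 with an estimated correlation). Gene calls for cap-h2-2 at 1 h were AT4G25580 (2.73), AT3G11110 (2.36, unmeasured in 3 groups), SUC2 (-0.73), CESA4 (-0.998), CESA8 (-1.0002), TSO2 (-1.24), SMR5 (-1.39), ADH1 (-1.44), SMR7 (-1.59), HRA1 (-1.75), SUS4 (-1.89), AT2G30540 (-2.92) and ATGA2OX1 (-2.98, unmeasured in 1 group). Gene calls for cap-h2-2 at 3 h were AT2G42560 (3.38), FRO1 (2.27, unmeasured in 3 groups), SMB (1.31), CYCB2;2 (0.75), BRN1 (0.57), CDKB2;2 (0.56), RBOHD (-0.91), SYN2 (-1.28), SUS4 (-1.69), SMR7 (-1.79), SMR5 (-1.93), GMI1 (-2.001), AT5G03480 (-2.77) and AT5G60250 (-3.10). Gene calls for crwn1/4 at 1 h were AT2G25625 (2.71, unmeasured in 2 groups), PDF2.1 (1.74), LBD41 (-0.95), HRE2 (-2.13), AT1G55230 (-3.84, unmeasured in 2 groups) and AT2G24910 (-4.02, unmeasured in 1 group). Gene calls for crwn1/4 at 3 h were MIR398a (1.78), HVA22B (1.57), BRN2 (1.00), BRN1 (0.62), SMR7 (-0.87), TK1A (-0.91), SMR5 (-1.25), TAT3 (-2.95) and CYP71B22 (-3.13, unmeasured in 1 group). Values with unmeasured groups rest on background and measure no difference.

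Arrays were split in other ways, on genes with complete values. With 35 splits each, only the real one reached its count in 14 comparisons (unadjusted). This argues against chance, not scan day where that differs. The real and highest other counts at 1 h, at 3 h and from 1 to 3 h were 6099 (543), 10216 (881) and 4865 (646) in Col-0. They were 8448 (371), 11423 (2) and 4581 (880) in cap-h2-2 and 10790 (2498), 10419 (1436) and 5042 (36) in crwn1/4. Against Col-0 they were 782 (162) at 0 h and 2164 (167) at 3 h for cap-h2-2, and 997 (741), 1555 (27) and 2248 (82) at 0, 1 and 3 h for crwn1/4. For cap-h2-2 vs Col-0 at 1 h, whose numbers pair the arrays, only 8 splits part as many pairs. That is too few for a share under 0.05, and counts were 2431 (212). Over all 35 splits, 2 were as large, with 2615 called when cap-h2-2 rep 1 and Col-0 rep 2 changed places. Of 100 draws for each difference in zeocin response, 2 were as large for cap-h2-2 at 1 h (2918 and 3371), 1 at 3 h (2696 and 162), 1 for crwn1/4 at 1 h (771 and 346) and 5 at 3 h (121 and 3046). Chance is not excluded for the last, and splits calling many times its count point to a structure of the arrays.

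Probes with no gene locus (12497), outside the report's comparisons, were often called after zeocin: 4123 (3599 lower) at 1 h and 4804 (4046 lower) at 3 h in Col-0, 1715 (1393 lower) and 3298 (2703 lower) in cap-h2-2, 6070 (5715 lower) and 3918 (3391 lower) in crwn1/4. Scaling does not account for the falls, which made up at least 68.9% of called probes under quantile normalization or normexp. Scan day stays open for their size: with the 0 h arrays shared out in either of 2 ways, the median fall on the 3 h array of scan day 4 was 0.420 or 0.643 of that on the other 3 h arrays in crwn1/4 and 0.505 or 0.512 in cap-h2-2. For genes called without that array, the slope of its changes on those of the other 3 h arrays was 0.736 or 0.851 in crwn1/4 and 0.852 or 0.774 in cap-h2-2, on both sides of the bound of 0.8 in each mutant, and part of the size may come from the scan day. At least 95% of those genes changed the same way on that array, which argues against scan day as the whole cause of the direction, while zeocin, time in solution and harvest time cannot be told apart.

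Proteasome genes (53, a list chosen after the values were seen) were lower in both mutants before and after zeocin: 36, 34 and 28 in cap-h2-2 and 39, 34 and 38 in crwn1/4 at 0, 1 and 3 h, and 0 higher. Medians were -0.30, -0.34 and -0.27, and -0.39, -0.37 and -0.40. Against slide, the highest median within a slide was -0.21. Against scaling, the highest median under quantile normalization or normexp was -0.25. With 2 of the Col-0 0 h arrays it was -0.28. The list came after these values, so chance in shared Col-0 arrays stays open. An effect of the mutations is a hypothesis, and Col-0 plants raised apart from both mutants remain an untested possible explanation.

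The DDR targets showed a smaller zeocin fold at 3 h in cap-h2-2 than in Col-0, by a median of -0.65. Slide does not account for it, the value with slide as a term being 0.978 of that without, nor do saturated spots, of which there were 0. A higher level before zeocin is consistent with the smaller fold: the median difference from Col-0 was 0.49 at 0 h and -0.16 at 3 h, the latter 0.240 of the difference in response. Whether the 0 h level comes from the mutation or from how the plants were raised was not tested.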

How the results depend on the processing

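Chosen after the data were seen were the fits without the slide 1 arrays, without the 3 h arrays of scan day 4 and without the crwn1/4 arrays with CRWN1 signal, and list tests with single arrays or members left out. Counts of called genes stayed within 1.5 times their value with a mean over probes, a stricter filter (all 36 arrays), quantile normalization, another variance model and replicate number as a block. The replicate block ended 1 list call, that of the root tip markers in the crwn1/4 difference at 1 h (adjusted p = 0.062), and changed no other call of a list or named gene. With slide as a term, counts were 461 at 1 h and 4417 at 3 h in Col-0, 3560 at 1 h and 7467 at 3 h in cap-h2-2 and 2677 at 1 h and 5072 at 3 h in crwn1/4. Further counts were 1996 at 0 h and 4136 at 1 h for cap-h2-2 against Col-0, 5121 at 1 h and 4130 at 3 h for the cap-h2-2 difference and 2964 at 0 h for crwn1/4 against Col-0. For the crwn1/4 difference they were 1187 at 1 h and 618 at 3 h. With slide as a random block (correlation 0.232), counts were 1776 at 0 h, 3952 at 1 h and 3410 at 3 h for cap-h2-2 against Col-0, 4761 at 1 h and 4408 at 3 h for the cap-h2-2 difference and 2542 at 0 h and 3421 at 3 h for crwn1/4 against Col-0. For the crwn1/4 difference they were 1877 at 1 h and 535 at 3 h. With scan date as a term, counts were 532 at 1 h and 4698 at 3 h in Col-0, 2415 at 1 h in cap-h2-2 and 2774 at 1 h and 6297 at 3 h in crwn1/4. They were 1283 and 1583 at 0 h for cap-h2-2 and crwn1/4 against Col-0 and 450 at 1 h for the crwn1/4 difference. On the compared arrays alone, counts were 2719 at 1 h and 2708 from 1 to 3 h in Col-0, 2500 from 1 to 3 h in cap-h2-2 and 113 at 1 h and 156 at 3 h for cap-h2-2 against Col-0. Further counts were 1232 at 1 h for the cap-h2-2 difference, 656 at 0 h, 223 at 1 h and 801 at 3 h for crwn1/4 against Col-0 and 291 at 1 h and 19 at 3 h for the crwn1/4 difference. Without the 3 h arrays of scan day 4, counts were 1341 at 3 h for cap-h2-2 against Col-0, 1186 at 3 h for crwn1/4 against Col-0 and 43 at 3 h for the crwn1/4 difference. Without the crwn1/4 arrays with CRWN1 signal, counts were 235 at 1 h and 17 at 3 h for the crwn1/4 difference. For the crwn1/4 difference, counts were 1386 at 1 h with normexp, 418 at 1 h in the series table, 73 at 3 h unfiltered and 474 at 1 h without the slide 1 arrays. With single arrays left out, counts ran from 334 to 1540 at 0 h, 1339 to 3780 at 1 h and 889 to 2532 at 3 h for cap-h2-2 against Col-0, 1798 to 4057 at 1 h and 1413 to 3493 at 3 h for the cap-h2-2 difference and 397 to 1855 at 0 h, 1004 to 1804 at 1 h and 1191 to 2365 at 3 h for crwn1/4 against Col-0. For the crwn1/4 difference they were 170 to 1689 at 1 h and 37 to 268 at 3 h. Of 106 list calls, 17 held with an estimated correlation, 45 ended without some single member, and counts with single arrays left out ran from 100 to 116. The correlation of both mutants' changes at 0 h moved from 0.53 to 0.66 with normexp and 0.31 with the Col-0 arrays split, and ran from 0.47 to 0.61 with single arrays left out. Direction turned at 1 h in Col-0 for AT2G20970 (-0.053 with slide) and AT5G32594 (-0.62 with slide, -0.53 with scan date). It turned at 1 h in cap-h2-2 for AT2G25890 (-0.36 with slide). Single-gene calls were lost in 22 cases with normexp, 15 with quantile normalization, 19 in the series table, 26 with slide, 25 with scan date and 55 on the compared arrays alone, of 245. Fewer arrays lower the residual degrees of freedom on the compared arrays alone; for the other settings the cause was not tested. Signal over background limits genes given with a bound.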

Other observations

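The tests on genes that differ at all times, on proteasome genes and on genes reduced by zeocin were chosen after the result was seen. Genes differed from Col-0 in both mutants at 0, 1 and 3 h: 3 were higher and 44 lower, where independent lists would share 0.0487 and 0.368. Comparisons of a time use the same Col-0 arrays. Simulated unchanged groups with these in common gave 0 and 0, as would independent lists of their sizes. They therefore cannot show how many shared calls the common arrays add. With the Col-0 arrays split between the mutants, means were 1.33 and 16.8, against 0.00775 and 0.0666 for independent lists. The higher ones, with the range of their 6 log2 fold changes, were AT1G16620 (1.60 to 1.89), AT2G43620 (0.71 to 1.23) and MRN1 (AT5G42600, 0.55 to 1.36). Of the lower ones, 23 are of the 53 proteasome genes, among them the core particle gene PAE1 (AT1G53850, -0.61 to -0.35) and the regulatory particle gene RPT3 (AT5G58290, -0.71 to -0.34).

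A hypothesis is that genes induced by zeocin are already higher in the mutants before zeocin, as the DDR targets may be. Of 274 genes raised over 4-fold at 3 h in crwn1/4, whose arrays take no part in the comparison, 54 (19.7%) were higher and 8 lower in cap-h2-2 at 0 h, against 2.11% higher among all genes (Fisher's exact test, 2 tests per mutant, p = 2.5e-36). That share met the bound of 10% set beforehand, and the highest number among 10000 random sets was 17. Of 177 genes reduced over 4-fold, 14 (7.91%) were also higher and 4 lower (median 0.16, against 0.24 for induced genes, Fisher's exact test of the shares higher, p = 6.7e-04), so part of the rise may not be specific to induced genes. Of 281 genes raised over 4-fold in cap-h2-2, 24 (8.54%) were higher and 19 lower in crwn1/4 at 0 h, against 1.35% of all genes (p = 8.9e-13, Fisher's exact test). That share missed the bound, and the random sets reached 12. Against the hypothesis, the median was 0.05 for induced and 0.23 for the 157 reduced genes (7 higher, 5 lower, p = 0.12 by the same exact test), and the question stays open for crwn1/4. Genes are not independent replicates, so these p-values are too small.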
